A study of Schizosaccharomyces pombe with 6 samples.

How the data were processed

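The series held 6 arrays of chromatin immunoprecipitated from fission yeast in log phase in rich medium. Per the labels, Xap5 carried an HA-TAP tag and was recovered on an anti-HA matrix after crosslinking with paraformaldehyde and dimethyl adipimidate, and H2A.Z (the product of pht1) carried a triple FLAG tag and was recovered with the M2 antibody. ChIP DNA was labelled with Cy5 (red) and whole-cell extract DNA with Cy3 (green) after random-primed amplification, per the labels' protocols. The arrays fell into 4 groups: Xap5 ChIP in wild type (2 arrays), H2A.Z ChIP in wild type (2 arrays), Xap5 ChIP in a pht1 deletion (1 array) and H2A.Z ChIP on an array labelled xap5 deletion (1 array). In the labels, wild-type array 2 of each protein is the control of that protein's deletion array, and each such pair lay on the same slide; it is called the labelled control. The replicate numbers follow only the order of deposit. No untagged strain was among the samples.

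The deposited scanner files gave intensity values in both channels from Agilent Feature Extraction 11.0.1.1 (Xap5 wild type 1), 9.5.1.1 (H2A.Z wild type 1) and 11.5.1.1 (the other arrays). Per the file headers, processed intensity was background-subtracted except in version 9.5.1.1 and was scaled by a linear dye factor per channel, and in most channels a multiplicative trend across the array was removed. The deposited log10 ratio column was checked against the processed intensities, and at most 3 probes on an array differed by more than 0.001. A deposited table of 47450 lines gave the linear ratio of normalized ChIP signal to extract signal for Xap5 and for H2A.Z, per its header. The header names neither the arrays behind the columns nor a genome build, so that table served only as a comparison.

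The log2 ratio of processed red to processed green intensity was computed from the deposited files for each of 41551 probes of 60 nt, without the 1417 control spots. Spots marked as outliers by the scanner software were set to missing (12 to 510 per array), and each array was centred on its median. No further dye or between-array normalization was applied. Probe sequences were matched exactly to the reference genome (RefSeq ASM294v3 with the PomBase annotation). There were 40396 probes with 1 match, 1053 with several and 102 with none, and the median spacing was 300 bp. All coordinates come from this match. Probes with 1 match were averaged over 5' regions (500 bp on either side of a gene start, 5258 regions) and gene bodies (the rest of the gene, 4663 regions) of 5356 protein-coding and noncoding genes.

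Tests used limma 3.58.1 in R 4.3.3 with the data.table package, version 1.17.8. A single fit of 4 group means over 6 arrays left 2 residual degrees of freedom, so a lone deletion array was assumed to vary like the wild types. Contrasts were deletion minus wild type, and group means were tested against 0, the array median; all tests were two-sided with Benjamini-Hochberg adjustment at 0.05. The difference from the labelled control stands beside each contrast and has no residual degrees of freedom and no test. The labels do not say whether arrays of a group came from separate cultures, so limma p-values of regions measure only the spread between these samples. The 2 wild-type arrays of each protein also differed in slide and in scanner software version, which are part of that spread. The 2 Xap5 wild types also differed in extract signal at ura4 and at mating-type (mat) probes without a match, so a difference of strain is part of it too. Across 5' regions the wild types differed with an SD of 0.34 for H2A.Z and 0.56 for Xap5. Each deletion array differed from its labelled control with an SD of 0.21 (H2A.Z) and 0.22 (Xap5). With the wider spread in the test, a count of 0 does not show that nothing changed. Gene lists were tested with camera at a preset correlation of 0.01 and, as an alternative, with an estimated correlation, adjusted over the lists. At the preset value camera sets a list against the spread across genes, taken as nearly independent, although divergent genes can share probes. Its p-value does not measure the spread between samples. For the single deletion arrays, the median difference from the labelled control was also placed among 10000 random lists of the same size matched on the wild-type level. Self-tests on simulated data used 50 changed regions per size, with all sizes planted together. Each array was drawn with the variance of the fit and no effect of slide or strain. The rates hold for that setting and do not give the chance of a call in these data. At a change of 1 on the log2 scale 8% to 18% of changed regions were called, at 2 between 82% and 90%, and at 3 between 98% and 100%. There were 13 and 6 false calls for H2A.Z and 14 and 7 for Xap5 in 5' regions and bodies. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared the tables and figures.

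The comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule named, per wild-type profile, the 8 highest and 5 lowest regions past the test with at least 2 probes. Per deletion contrast it named up to 8 regions in each direction past the test, filled to 8 with regions that differed from both wild-type arrays by more than these differed from each other. For each list it took up to 4 members with the largest values, and it always took pht1 and xap5; only protein-coding genes with a name were eligible, and divergent genes that share a 5' region were named together. The 18 lists were ribosomal proteins, mitochondrial ribosomal proteins, ribosome biogenesis, proteasome, core histones, glycolysis, chaperones, stress response, meiosis and sporulation, iron uptake, phosphate acquisition, nitrogen starvation and mating, hexose transporters, ergosterol biosynthesis, Tf2 retrotransposons, tRNA genes, snoRNA and snRNA genes, and subtelomeric genes (within 50000 bp of a chromosome end).

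Alternatives were normexp background correction with an offset of 50, scaling each array by its median absolute deviation, centring on the mode, loess within arrays with a span of 0.3, a filter on dim probes, the median of probes, 250 bp regions, at least 2 probes per region, limma with trend and robust variance, each wild-type array left out, and the slide as a block. Normexp had been planned on mean signals, which only 1 file holds, so it was run on median signals. Control spots, the 102 probes without a match and the 1053 probes with several matches were left out of the gene regions. Probes with several matches were used in the classes of genomic region, and probes without a match only in the checks of the extract channel.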

Results

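Xap5, a conserved chromatin-associated protein, and the histone variant H2A.Z were each mapped by ChIP-chip in fission yeast, with 2 wild-type arrays per protein, 1 array of Xap5 in cells that lack pht1 (the H2A.Z gene) and 1 array of H2A.Z labelled xap5 deletion. The values are log2 ratios of ChIP over whole-cell extract, relative to the median of each array. Median green signal over local background was 312 and 90.3 on the Xap5 wild-type arrays 1 and 2, 421 on the pht1 deletion array, 212 and 34.0 on the H2A.Z wild-type arrays, and 31.9 on the array labelled xap5 deletion. Red signal over background was 692, 156 and 768 for the Xap5 arrays and 415, 270 and 232 for the H2A.Z arrays, in the same order. The ratios spread differently, with SDs of 0.77, 0.37 and 0.38 for the Xap5 arrays and 0.75, 0.57 and 0.67 for the H2A.Z arrays. The number of arrays limits the precision, and the deletion arrays have no replicate.

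The deleted genes were read first, in the extract channel. On the pht1 deletion array the 1 probe inside the coding part of pht1 (SPBC11B10.10C, II: 1502203 to 1503444) lay at -8.48 relative to the array median, against -0.94 on its labelled control and -0.94 to 0.16 on the other 5 arrays. For xap5 (SPCC1020.12C, III: 755252 to 756290) the mean of the 3 coding probes was 0.07 on the array labelled xap5 deletion, against 0.23 on its labelled control and -0.45 to 0.23 on the other 5 arrays. The xap5 probes therefore went against the label of that array, and each direction given for it below is for the array labelled xap5 deletion, not for cells shown to lack the gene. The ChIP channel signal of these probes, relative to the array median, was 1.08 on that array and 1.08 on its control. Probes outside the coding parts check nothing.

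**Figure D1:**
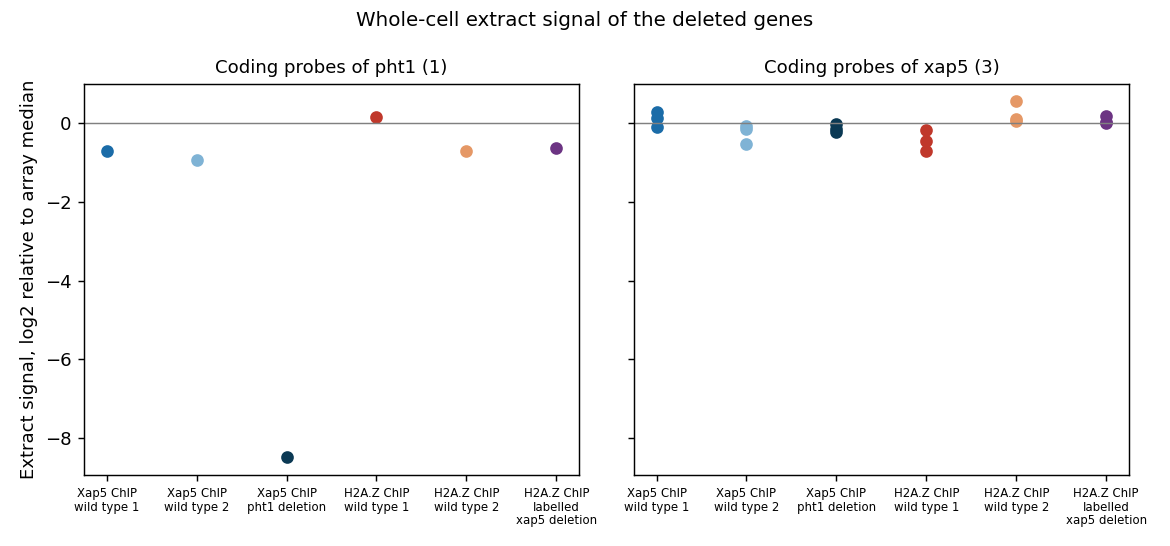
Whole-cell extract signal of the coding probes of pht1 (1 probe) and xap5 (3 probes) on each of the 6 arrays, in log2 relative to the array median. The pht1 probe stood at -8.48 on the pht1 deletion array, and the xap5 mean stood at 0.07 on the array labelled xap5 deletion.

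H2A.Z in wild type asked which gene starts and bodies carry the variant. Among named protein-coding genes, it was highest in 5' regions at nuf2 (I: 4321520 to 4323223), which encodes a kinetochore protein, at 2.27 ± 0.21 (limma SE, n = 2; 2.54 and 2.01 on the arrays). Next came the shared region of swd2, a subunit of the COMPASS histone methyltransferase, and wbp4 at 2.25 ± 0.24, the nucleoporin gene nup132 at 2.09 ± 0.19, met7 at 1.90 ± 0.23, the shared region of the DNA repair genes lig4 and ung1 at 1.89 ± 0.25, and the gamma-tubulin gene gtb1 at 1.88 ± 0.22 (limma adjusted p = 0.0033 for each, above 0 on 2 of 2 arrays). The lowest 5' regions of named protein-coding genes belonged to the pyruvate decarboxylase gene pdc102 near a chromosome end (I: 5552811 to 5554529) at -1.48 ± 0.18 and to a group of phosphate-starvation genes and neighbours on chromosome II, with pho84, a phosphate transporter, at -1.44 ± 0.21, ecl3 at -1.32 ± 0.26 and the acid phosphatase gene pho1 at -1.30 ± 0.19. The methionine synthesis gene met6 stood at -1.41 ± 0.32 (limma adjusted p = 0.0111, the largest of the 5). At xap5 itself H2A.Z stood at 1.16 ± 0.19 (limma adjusted p = 0.00447) and at pht1 at -0.54 ± 0.27 (limma adjusted p = 0.152). Of 5258 regions, 1351 passed the limma test above the array median and 445 below it. That count of 1796 was 8 without H2A.Z wild type 1, 724 without H2A.Z wild type 2 and 2850 without Xap5 wild type 1 or 2, each array left out singly. With an H2A.Z array left out, the spread came from the Xap5 pair alone, and the remaining H2A.Z array was assumed to vary like it.

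In the bodies of named protein-coding genes H2A.Z was highest at dal2, an allantoicase gene, at 1.90 ± 0.25, at cda1, a chitin deacetylase gene, at 1.82 ± 0.26, at nuf2 at 1.76 ± 0.16, at dgc1 at 1.75 ± 0.24, at the mitochondrial tether gene mdm12 at 1.73 ± 0.23, at mmt1 at 1.72 ± 0.24 and at the THO complex gene tho3 at 1.71 ± 0.21 (limma adjusted p = 0.0136 for each). The meiotic gene mcp6 stood at 1.61 ± 0.25 (limma adjusted p = 0.0147). Of these genes, pdc102 again had the lowest body at -1.47 ± 0.17, followed by tif51 at -1.02 ± 0.16, mim1 at -1.02 ± 0.19, eta2 at -0.98 ± 0.16 and mpc1 at -0.96 ± 0.21. All 13 had the same sign on both arrays. The xap5 body stood at 0.99 ± 0.16 (limma adjusted p = 0.0149). Of 4663 bodies, 731 passed the limma test above the median and 272 below it. Without H2A.Z wild type 1 the count of 1003 became 0 (limma, 567 at an unadjusted p under 0.05), without H2A.Z wild type 2 it was 235, and without Xap5 wild type 1 or 2 it was 1601, with the same limit on the spread.

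Several gene lists lay low in H2A.Z at their starts. Over the 15 glycolysis genes the 5' median was -0.68 (limma camera adjusted p = 8.15e-07), with 8 of 15 members past the test over all regions and 10 when adjusted over the list alone, all below 0; eno101 at -1.06 and gpm1 at -0.95 were examples. The 138 ribosomal protein genes had a median of -0.35 (limma camera adjusted p = 6.29e-13), with 1 above and 22 below over all regions and 0 adjusted over the list alone by limma. For 72 snoRNA and snRNA genes the median was -0.64 (limma camera adjusted p = 7.47e-14), with 3 above and 33 below over all regions and 4 above and 44 below adjusted over the list alone; snoZ7 lay at -1.56. Of 21 measured subtelomeric genes 16 lay below over all regions and 17 adjusted over the list alone (median -0.82, limma camera adjusted p = 8.99e-13), with fah1 at -1.28. The 139 tRNA genes had a median of -0.34 (limma camera adjusted p = 2.38e-10), with 25 below and 1 above over all regions and 17 below adjusted over the list alone. Smaller groups also lay low: 15 chaperones at -0.44 (limma camera adjusted p = 0.00573, 6 below and 1 above), 6 phosphate genes at -0.38 (limma camera adjusted p = 0.00573, 2 below), 8 hexose transporters at -0.39 (limma camera adjusted p = 0.0119, 2 below, ght8 at -0.88), 9 core histones at -0.29 (limma camera adjusted p = 0.0126, all 9 below 0, 0 past the limma test) and 30 proteasome genes at -0.20 (limma camera adjusted p = 0.0149, 6 below and 3 above). The counts of these smaller groups were the same when adjusted over the list alone, except for 2 chaperones above. The 39 mitochondrial ribosomal protein genes stood on the other side, with a median of 0.39 (limma camera adjusted p = 0.0213), 14 above over all regions and 15 adjusted over the list alone, such as mrpl50 at 1.69 and mrps17 at 1.26. With an estimated correlation no list call held: adjusted p = 0.253 with an estimated correlation for the subtelomeric genes, 0.266 for glycolysis, 0.395 for the hexose transporters and 0.368 for the other 8 lists.

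Ribosome biogenesis (median 0.03), stress response (-0.04), meiosis and sporulation (0.07), iron uptake (-0.26), nitrogen starvation and mating (0.00) and ergosterol biosynthesis (0.03) did not pass in 5' regions (limma camera adjusted p from 0.160 to 0.257). They were mixed: 25 of 132 meiosis genes lay above and 11 below over all regions (24 and 11 adjusted over the list alone), among them mug37 at 1.22, and in the iron list str2 stood at 1.09 and str3 at -1.23. In bodies the ribosomal protein genes (-0.40), ribosome biogenesis (-0.17), proteasome (-0.25), core histones (-0.47), glycolysis (-0.35), snoRNA and snRNA genes (-0.89, 4 measured) and subtelomeric genes (-0.73, 15 of 16 past the test) lay low at limma camera adjusted p from 1.14e-09 to 0.0258. With an estimated correlation these calls were lost too (adjusted p = 0.335 with an estimated correlation for the subtelomeric genes and 0.434 for the others). Both measured Tf2 bodies lay above the median (0.75, limma camera adjusted p = 0.195).

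Along 4266 genes of at least 1000 bp, H2A.Z peaked in the 500 bp after the gene start. Between the start and 250 bp downstream the mean was 0.38 and 0.25 on wild-type arrays 1 and 2 and 0.36 on the array labelled xap5 deletion. Xap5 showed no such peak. It was highest around gene ends, at 0.14 and 0.11 on the wild types in the 250 bp before the end. In the 250 bp after the end it stood at 0.09 and 0.13 on the wild types and 0.15 in the pht1 deletion. Upstream of gene starts, between 500 and 250 bp before the start, Xap5 stood at 0.02 and 0.10 on the wild types and 0.10 in the pht1 deletion. The contrast between starts and ends was thus clearest on wild type 1. Among classes of region, H2A.Z averaged 0.19 ± 0.03 (SD, n = 2) in 5' regions and 0.05 ± 0.03 in bodies of protein-coding genes, -0.42 ± 0.12 in convergent intergenic sequence, -0.99 ± 0.02 in subtelomeres, -1.44 ± 0.52 in centromeres and -1.66 ± 0.76 in ribosomal DNA. Xap5 averaged 0.85 ± 0.30 over Tf2 retrotransposons and 0.27 ± 0.13 over the mating-type region, against 0.00 ± 0.05 in 5' regions. H2A.Z over Tf2 differed between the wild types (1.04 and 0.04), as did Xap5 over tRNA genes (-0.34 and 0.28). These class means carry no test.

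**Figure D2:**
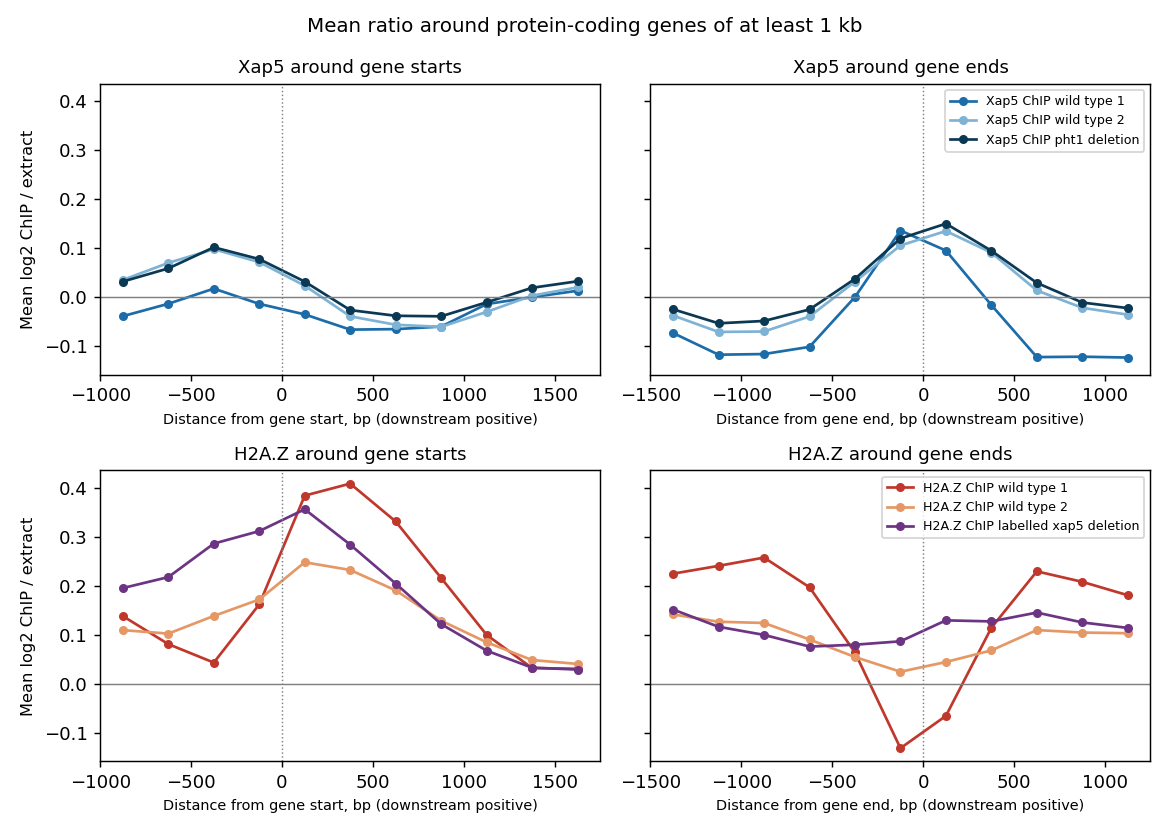
Mean log2 ChIP over extract per 250 bp bin around the starts and ends of 4266 genes of at least 1000 bp, 1 line per array, with distance in bp on the horizontal axis. H2A.Z peaked after the start, at 0.38 and 0.25 on the wild types in the first 250 bp and 0.41 and 0.23 in the next. Xap5 was highest around the end, at 0.14 and 0.11 on the wild types in the 250 bp before it and 0.09 and 0.13 after it.

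**Figure D3:**
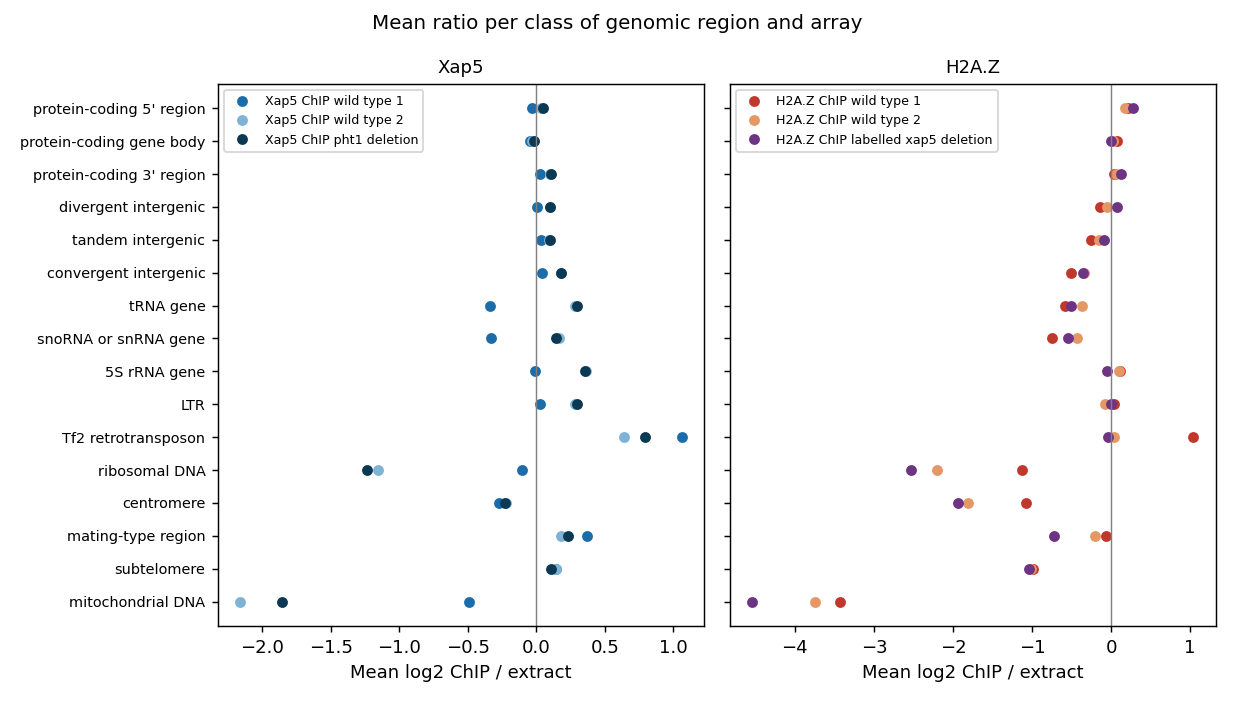
Mean log2 ChIP over extract per class of genomic region, 1 point per array, Xap5 on the left and H2A.Z on the right, on horizontal axes of different range. Tf2 retrotransposons were highest for Xap5 (1.06 and 0.64 on the wild types), and subtelomeres lay at -0.98 and -1.01 for H2A.Z.

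Xap5 in wild type asked where the protein sits relative to the extract. The 5' regions of dcr1, which encodes Dicer (III: 1504949 to 1510557), and of cuf1, a copper-sensing regulator (I: 407714 to 409845), lay highest at 1.47 ± 0.20 (limma SE, n = 2, adjusted p = 0.0341) and 1.35 ± 0.19 (limma adjusted p = 0.0458). A further region, at SPAC17A5.19, was chosen after its values were seen and stood at 1.25 ± 0.18 (limma adjusted p = 0.0486). The 4 regions past the test on the low side all belonged to glycolysis and fermentation enzymes: tdh1 (II: 2807595 to 2809051) at -1.78 ± 0.19, pgk1 (II: 4157821 to 4159461) at -1.56 ± 0.19, adh1 (III: 1591292 to 1592889) at -1.49 ± 0.18 (limma adjusted p = 0.0278 for these) and fba1 (II: 1688321 to 1689599) at -1.41 ± 0.18 (limma adjusted p = 0.0318). All 7 had the same sign on both wild-type arrays and on the pht1 deletion array. Only these 7 of 5258 regions passed, with 1298 at an unadjusted p under 0.05. The count moved with the arrays: 1672 without Xap5 wild type 2, 17 without Xap5 wild type 1 and 124 without H2A.Z wild type 1 or 2, each left out singly. With a Xap5 array left out, the spread came from the H2A.Z pair alone, so those counts do not measure how far the Xap5 arrays matched. It moved with the settings too, from 0 by limma with trend and robust variance (1318 at an unadjusted p under 0.05) to 705 after array scaling (392 above and 313 below). In bodies 0 of 4663 regions passed by limma (1100 at an unadjusted p under 0.05, smallest adjusted p 0.111), but 747 did without Xap5 wild type 2.

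Glycolysis genes as a group were low in Xap5, with a 5' median of -1.04 and 14 of 15 below 0 (limma camera adjusted p = 2.38e-10); 4 passed over all regions and 12 adjusted over the list alone, each below 0. Ribosomal protein genes had a median of -0.39 (limma camera adjusted p = 4.68e-12), with 0 past the limma test over all regions, and 20 below and 1 above adjusted over the list alone. The 9 core histone genes lay at -0.47 (limma camera adjusted p = 0.0130; 0 past the limma test over all regions and 2 below adjusted over the list alone). With an estimated correlation none held (adjusted p = 0.326 with an estimated correlation for glycolysis and 0.650 for the other lists). In bodies glycolysis (-0.75, 11 of 15 below adjusted over the list alone), ribosomal proteins (-0.49, 13 of 79) and chaperones (-0.44, 8 of 13 below and 1 above) lay low at limma camera adjusted p of 2.79e-07, 1.76e-09 and 0.00252, with 0 members past the limma test over all regions. These calls were lost as well (adjusted p = 0.467 with an estimated correlation for glycolysis and 0.897 for the others). Hexose transporters (0.37) and nitrogen starvation and mating genes (0.32) had the highest 5' medians and did not pass (limma camera adjusted p = 0.144 for each).

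Whether Xap5 and H2A.Z occupy the same genes was read from the correlation across genes, which are not independent replicates. Over 5' regions Pearson r averaged 0.101 over the 4 pairs of a Xap5 and an H2A.Z wild-type array (0.031 to 0.166), and Spearman rho averaged 0.096 (0.026 to 0.163). In bodies r averaged 0.081 (0.015 to 0.140). Without H2A.Z wild type 2 r averaged 0.053 over 5' regions and 0.025 in bodies, and without H2A.Z wild type 1 it averaged 0.149 and 0.137. Between the wild-type arrays of the same protein, r over 5' regions was 0.469 for Xap5 and 0.888 for H2A.Z. The low value for Xap5 limits how high r between the proteins could be. The authors' deposited table of ratios gave r = 0.080 and rho = 0.078 for Xap5 and H2A.Z over 5' regions. Its columns followed wild type 1 of each protein closely (r = 0.987 and 0.999 across probes). It is therefore no separate check on that pair of arrays, which gave r = 0.075. Genes differed in which protein they carried: dcr1 had Xap5 at 1.47 ± 0.20 and H2A.Z at -0.66 ± 0.20 (limma adjusted p = 0.0306), and xap5 had H2A.Z at 1.16 ± 0.19 and Xap5 at -0.16. At cuf1, also high in Xap5 at 1.35, H2A.Z stood at 0.39 ± 0.19 (limma adjusted p = 0.143). Of the 4 glycolysis and fermentation genes low in Xap5, pgk1, adh1 and fba1 were also low in H2A.Z, at -0.85, -0.68 and -0.59, and tdh1 stood at -0.25 (limma adjusted p = 0.336).

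Xap5 in the pht1 deletion asked whether Xap5 occupancy needs H2A.Z. The limma test took its spread from wild-type arrays on different slides, so 0 calls do not show that Xap5 was unchanged. The largest difference from the labelled control was at the 5' region of gmh6 (II: 4407285 to 4409706), 1.26 higher (contrast with both wild types 1.43 ± 0.33, n = 1 against 2, limma adjusted p = 0.999). Others not past the test stood at 0.73 for mso1, 0.72 for mpe1, 0.70 for fap2, 0.69 for rad24, a 14-3-3 protein gene, 0.68 for the region shared by the mitotic kinase gene mik1 and ssb1, and 0.67 for frs1. On the low side ldb1 stood at -0.69, omt2 at -0.63, omh5 at -0.62, the heterochromatin gene rik1 at -0.57, nth1 at -0.57, pcc1 at -0.56, mug150 at -0.56 and sea4 at -0.53. Body values ran from 0.51 to 0.73 for qtr1, rib7, rps1401, tim10, hxk2, wss1, pek1 and cki3 and from -0.69 to -0.51 for cox19, isa1, mms2, apt1, sap14, isd11, atp11 and ppk3. The 7 regions called in wild type were picked for extreme values on the wild-type arrays themselves. A further array would tend to lie nearer the array median there without any change. Among them, tdh1 at -1.11, pgk1 at -1.12, adh1 at -1.09 and fba1 at -1.32 stood above both wild types in the pht1 deletion. Against the control these 4 were higher by 0.53, 0.57, 0.46 and 0.06. In the same array dcr1 at 0.99 and cuf1 at 1.13 stood below both, and SPAC17A5.19 at 1.67 stood above both. None of these contrasts passed the limma test. By limma, 0 of 5258 5' regions (21 at an unadjusted p under 0.05) and 0 of 4663 bodies (24) passed; without Xap5 wild type 2, 292 5' regions did (246 higher and 46 lower), with the spread from the H2A.Z pair alone. Against the labelled control, 1 region of each type differed by more than 1, gmh6 and the body of ura4. The latter was chosen after its values were seen, and at its probe III: 116002 to 116061 the extract of the pht1 deletion array stood at -7.58, against 0.52 on the control.

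Among the gene lists, 3 passed in 5' regions and 1 in bodies, and each stood nearer to 0 against the labelled control than against both wild types. Ribosomal protein genes stood 0.25 above the wild-type mean in 5' regions (limma camera adjusted p = 9.16e-07) and 0.38 in bodies (limma camera adjusted p = 1.43e-10), but 0.05 and 0.12 above the labelled control, at percentiles 58.3 and 99.1 of random lists. The tRNA genes stood at 0.30 (limma camera adjusted p = 1.16e-06) and 0.07 above the control (percentile 99.7), and snoRNA and snRNA genes at 0.23 (limma camera adjusted p = 0.0336) but at -0.02 against the control, the opposite sign (percentile 14.6). In these lists the wild types differed by more, with Xap5 wild type 1 minus wild type 2 at -0.44 for ribosomal proteins, -0.51 for tRNA and -0.34 for snoRNA and snRNA genes in 5' regions; without Xap5 wild type 1 the last list stood at -0.02. No call held with an estimated correlation (adjusted p = 0.795 with an estimated correlation in 5' regions and 0.888 in bodies), and 0 members passed by limma. Across 5' regions Pearson r between the pht1 deletion array and its control was 0.759, against 0.469 between the wild types. The difference had an SD of 0.22, against 0.56 between the wild types. These wild types also differed in slide, in software version and in extract signal at ura4 and at unmatched mat probes. Their spread is therefore not that of replicate arrays alone.

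H2A.Z on the array labelled xap5 deletion asked whether H2A.Z occupancy needs Xap5, with the doubt about the label given above. The limma spread came from wild-type arrays on different slides, so a count of 0 below does not show that nothing changed. The lowest regions against the labelled control lay beside the mating-type locus mat1: SPBC23G7.10C (II: 2118146 to 2119478, chosen after its values were seen) at -1.56 in its 5' region and -2.03 in its body, and the neighbouring DNA glycosylase gene mag2 (II: 2120257 to 2121050) at -1.19 and -1.20. The 5' contrast with both wild types was -1.77 ± 0.33 for SPBC23G7.10C (n = 1 against 2, limma adjusted p = 1.0) and -1.20 ± 0.31 for mag2. On the high side pdc102, the lowest named protein-coding gene in wild type, stood 0.86 higher in its 5' region and 1.21 higher in its body. Other 5' values not past the test were 0.74 for dcp1, a decapping enzyme gene, 0.69 for omh5 and lsc1, 0.68 for eng2, 0.64 for vam6, 0.57 for mug132 and 0.52 for meu1, and on the low side -0.64 for fhn1 and rps2, -0.58 for pma1, the plasma membrane proton pump gene, -0.54 for rpl13, -0.51 for sap1, which encodes a switch-activating DNA-binding protein, and -0.48 for adh1 and rps901. Body values ran from 0.52 to 0.76 for oms1, dcp1, dad4, smg1, meu31, csm1 and cyb502 and from -0.77 to -0.57 for tef101, tef103, mug106, pma1, knh3, but2 and rpl502. By limma, 0 of 5258 5' regions (5 at an unadjusted p under 0.05) and 0 of 4663 bodies (19) passed. Only SPBC23G7.10C passed in an alternative, in 5' regions without Xap5 wild type 1 or without wild type 2 (-1.77 ± 0.29, limma adjusted p = 0.0116, the count then 1) and in bodies with normexp (-3.32 ± 0.34, limma adjusted p = 0.0149).

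The values were lowest over 6 kb (II: 2114001 to 2120000), a stretch chosen after the values were seen. There 30 of 31 probes lay below the labelled control, with a median difference of -1.63. The median H2A.Z ratio was 0.74 and 0.07 on the wild types and -1.41 on the array labelled xap5 deletion. Genes with probes in the stretch were prl103, which overlaps its edge, SPNCRNA.388, SPBC23G7.10C and SPNCRNA.5499. The genes mat1-Mi and mat1-Mc lie within it but had no probe in use. Low values ran on into the next window (II: 2120001 to 2122000), which holds mag2, at -1.06 against the labelled control and -0.81 against H2A.Z wild type 1. Its 3 windows were the only ones of 6049 windows of 2000 bp in which H2A.Z lay more than 1 below both wild types; 0 lay more than 1 above both, with no test.

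**Figure D4:**
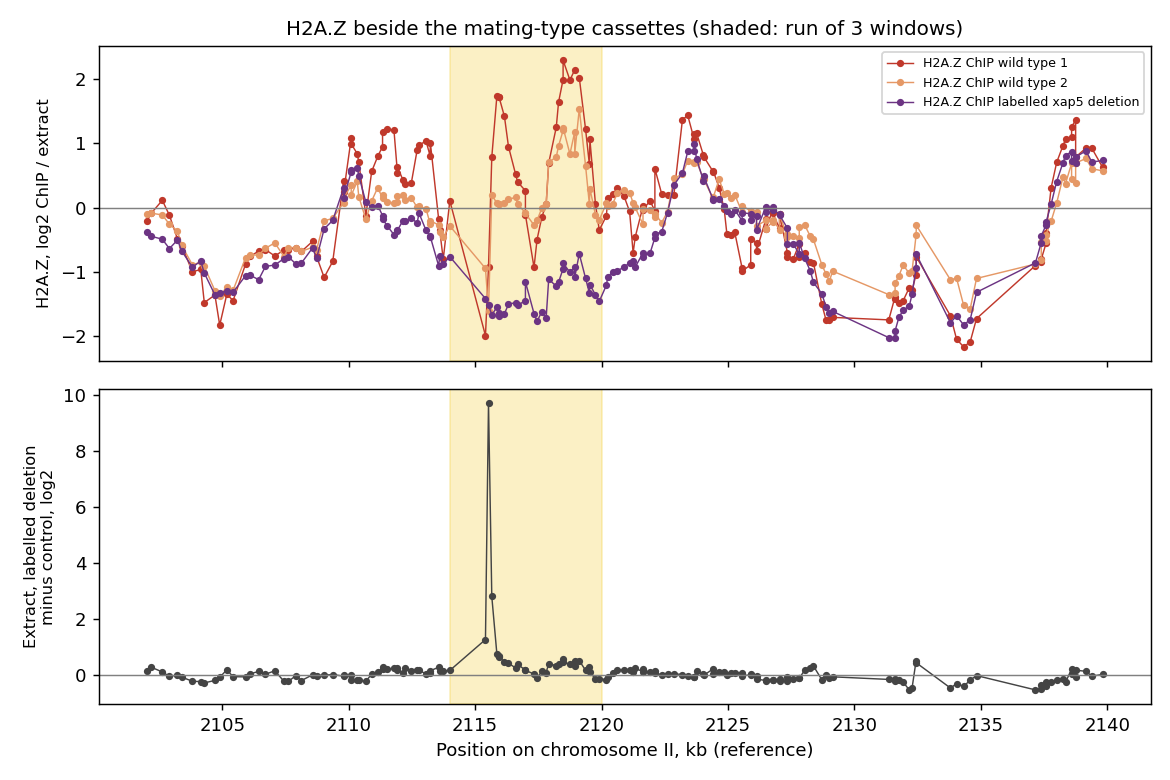
The top panel shows H2A.Z log2 ChIP over extract per probe on the 3 H2A.Z arrays, against position on chromosome II in kb. The bottom panel shows the log2 difference in extract signal, the array labelled xap5 deletion minus its labelled control. Over the 6 kb stretch the array labelled xap5 deletion had a median ratio of -1.41, against 0.74 and 0.07 on the wild types.

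Glycolysis and ribosomal protein genes lay below other genes on the array labelled xap5 deletion. The median of all 5258 5' regions stood 0.11 above the labelled control. All 15 glycolysis 5' regions were under the labelled control, with a median of -0.29, and the contrast with both wild types was -0.32 (limma camera adjusted p = 2.05e-09; adh1, eno101 at -0.48 and fba1 at -0.46 among them). For ribosomal proteins 123 of 138 were under the control, with a median of -0.20 and a contrast of -0.14 (limma camera adjusted p = 1.86e-17). The wild types already differed in the same direction in these 5' lists. Unscaled, H2A.Z wild type 1 minus wild type 2 had a median of -0.07 for glycolysis, -0.11 for ribosomal proteins and -0.22 for core histones. After array scaling the medians against the control were -0.15 for glycolysis (13 of 15 below) and -0.09 for ribosomal proteins (105 of 138 below). All 9 core histones were under it too in unscaled values (-0.16, percentile 3.03 of random lists; contrast -0.12, limma camera adjusted p = 0.0465). With an estimated correlation the calls were lost (adjusted p = 0.359 with an estimated correlation for glycolysis and 0.606 for the other lists). In bodies, ribosomal proteins (-0.24 against the control), glycolysis (-0.30), hexose transporters (-0.32) and phosphate genes (-0.22) lay at percentiles from 0 to 2.69, chaperones (-0.14) at 2.87 and nitrogen starvation and mating genes (-0.03) at 7.68. These 6 passed at limma camera adjusted p from 1.31e-05 to 0.0274 and not with an estimated correlation (adjusted p = 0.452 with an estimated correlation). In all lists 0 members passed by limma. Pearson r with the labelled control across 5' regions was 0.951, against 0.888 between the wild types.

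Change was also set against wild-type level. Spearman rho across 5' regions between the difference from the labelled control and the level on the other wild-type array was 0.505 for H2A.Z, so regions high in wild type tended to be higher still on the array labelled xap5 deletion. The ratios spread more widely on that array, with an SD 1.22 times that of its control, and after array scaling rho was -0.066. For Xap5 in the pht1 deletion rho was 0.004.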

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

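The tests of the xap5 label and of the mating-type stretch were chosen after the results were seen; the tests of the extract channel for the gene lists were chosen before, and those after array scaling after. Read by itself, the extract channel, which is the denominator of the ratios, held both of the following signals. The extract signal of the 36 mat probes without a match in the reference was 0.677 higher, in the median, on the array labelled xap5 deletion than on its control. The extract signal of the 3 ura4 coding probes averaged 0.448 on Xap5 wild type 2 and -5.88 on Xap5 wild type 1, where all 3 lay more than 3 below the array median; on each of the other 4 arrays 1 of the 3 did (means -3.30 to -2.51), and the differences were not tested.

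The xap5 coding probes stood at the wild-type level on the array labelled xap5 deletion. Probes that could not see a deletion cannot be told apart from this. Their extract signal was at least 29.4 times the background, but on none of the 6 arrays did they read a loss. No other array was labelled as lacking xap5, so this check could not count against such probes. A sample that carries xap5, through a wrong label or a missing deletion, remains a candidate explanation, since the extract difference from the control was -0.158, within the spread of the other arrays. Which of these applies stays open, and so does what the array says about cells without Xap5.

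H2A.Z lay far below the labelled control over 6 kb beside mat1 on the array labelled xap5 deletion. The extract signal of the stretch was 0.361 higher in the median than on the control. Extra DNA would raise the ChIP channel too. Even with no such rise, 0.361 is less than the fall of 1.63 in the ratio. After scaling for the wider spread of ratios on that array, -1.38 remained. A structure of the mating-type region that differs between that strain and its control may account for the low H2A.Z ratios. All 36 unmatched mat probes had more extract signal than on the control (0.677 in the median). A probe inside the stretch (II: 2115500 to 2115559) stood at 0.75 in the extract, against -8.95 on the control and -7.08 on H2A.Z wild type 1. On the Xap5 arrays that probe stood at -0.35, 0.81 and -0.01, so there the H2A.Z wild types were the ones that stood apart. This explanation stays open, because the unmatched mat probes differed by -0.33 in the median between the pht1 deletion array and its control. Loss of xap5 cannot be told apart from the strain, because 1 array carries the label and its xap5 probes differed from the control by -0.158.

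H2A.Z ratios of glycolysis and ribosomal protein genes lay below the labelled control on the same array. A wider spread of ratios as the whole cause is argued against. After array scaling both lists lay at percentile 0 of 10000 random lists, with 13 of 15 and 105 of 138 members below the control. The random lists do not measure the spread between arrays or the shared behaviour of a list's genes. Unscaled, H2A.Z wild type 1 minus wild type 2 had medians of -0.07 for glycolysis and -0.11 for ribosomal proteins. Variation between arrays therefore stays open. For glycolysis, the extract channel could contribute, since extract signal was 0.169 higher than on the control, beside ratio medians of -0.29 before and -0.15 after scaling. For ribosomal proteins the extract difference was 0.0619, beside ratio medians of -0.20 before and -0.09 after scaling, and the extract and the ChIP channel cannot be told apart because 1 array holds both. Loss of xap5 was not tested here.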

How the results depend on the processing

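The alternatives for the deletion checks, the change against level and the authors' table in the correlation were chosen after the data were seen; the others were planned. No paired analysis was possible because the replicate numbers follow only the order of deposit; the labels pair each deletion array with a control on its slide, which with 1 pair per protein leaves no residual degrees of freedom for a test. With a wild-type array left out, the spread came from the other protein's pair alone. Signal over background was 31.9 or more in both channels of each array, and the number of arrays limits the precision. The slide as a block gave counts past 1 against the labelled control of 2 (H2A.Z) and 1 (Xap5) in 5' regions and 3 and 1 in bodies, without a test.

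For H2A.Z on the array labelled xap5 deletion the 5' count ranged from 0 to 1 with an array left out, and the body count was 1 with normexp. For Xap5 in the pht1 deletion the 5' count ranged from 0 to 292. The Xap5 5' count in wild type (7; 3 above and 4 below) was 202 with normexp (159 and 43), 705 with array scaling (392 and 313), 252 with loess (186 and 66), 15 in 250 bp regions, 0 by limma with trend and robust variance (1318 at an unadjusted p under 0.05) and 17 to 1672 with an array left out; with the mode it was 5 (1 and 4). In bodies it was 248 with normexp, 397 with scaling and 0 to 747 with an array left out. The H2A.Z counts ranged from 8 to 2850 in 5' regions and 0 to 1601 in bodies with an array left out. Their split of 1351 above and 445 below became 1631 and 274 with loess, and in bodies 731 and 272 became 863 and 166 with the mode.

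The H2A.Z mean in 5' regions minus bodies (0.14) was 0.22 with normexp, 0.13 with scaling, 0.27 with loess and 0.18 with the median of probes. The 13 list calls on the H2A.Z array labelled xap5 deletion and the Xap5 array of the pht1 deletion became 0 with an estimated correlation and 9 to 17 with an array left out. The snoRNA and snRNA 5' list for Xap5 in the pht1 deletion (0.23) reversed to -0.025 without Xap5 wild type 1 and was 0.48 without Xap5 wild type 2. The pht1 extract difference (-7.55) was -0.42 with normexp and -6.18 as scanned, and the xap5 one (-0.16) was -0.38 and -0.20. With normexp the pht1 probe stood at -1.48 on the deletion array, against -1.06 to 0.34 on the other arrays, so the loss was hardly visible. Change against level for H2A.Z (0.505) was -0.066 after scaling. In each case without a stated reason the cause was not tested.

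With an array left out, the mean correlation of Xap5 and H2A.Z ranged from 0.053 to 0.149 over 5' regions (0.101) and from 0.025 to 0.137 in bodies (0.081). Of the values that answer a comparison 122 were the same and 36 moved under an alternative; of the others 481 were the same, 63 weaker, 54 moved and 1 reversed. Of the 37 list calls over all contrasts, no other alternative ended more than 6. The values of the authors' deposited table could not be run for the 8 counts, since it holds a single value per protein.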

Other observations

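The following values and groups were chosen after the results were seen. On the array labelled xap5 deletion, the 21 measured subtelomeric 5' regions had a median 0.12 above the labelled control, near the 0.11 of all 5258 5' regions but at percentile 99.99 of random lists matched on their low wild-type level; the contrast with both wild types was 0.10 (limma camera adjusted p = 0.249). The 3 windows of 2000 bp in which H2A.Z lay more than 0.6 above both wild types were contiguous (I: 5552001 to 5558000) and held pdc102; they stood at 0.99, 0.95 and 0.97 above the control, from wild-type levels of -1.73 to -1.41. Besides the lists in the report, those below the control in 5' regions at percentiles from 0.01 to 2.65 were hexose transporters (-0.31, 7 of 8 below), tRNA genes (-0.07, 94 of 139), stress response genes (-0.11, 11 of 20), snoRNA and snRNA genes (-0.10, 44 of 72) and chaperones (-0.11, 11 of 15). None of these passed against both wild types, where their contrasts were -0.09, 0.02, -0.0025, 0.01 and 0.04 (limma camera adjusted p from 0.0916 to 0.581), of the opposite sign for tRNA, snoRNA and snRNA genes and chaperones. For the same lists, in that order, H2A.Z wild type 1 minus wild type 2 had medians of -0.36, -0.225, -0.15, -0.19 and -0.10. Except for chaperones, these gaps between the wild types were larger than the differences from the control. Mitochondrial DNA, which has no nucleosomes, had the lowest H2A.Z class mean of -3.59 in wild type.

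For Xap5 in the pht1 deletion, the glycolysis bodies stood 0.25 above the labelled control (percentile 99.3 of random lists), the meiosis and sporulation bodies at -0.03 (percentile 0.39) and the chaperone 5' regions at 0.17 (percentile 98.0). Against both wild types these lists stood at 0.01, 0.0054 and -0.04 and did not pass (limma camera adjusted p = 0.550, 0.550 and 0.931), with the opposite sign for the last 2. Windows in which Xap5 differed by more than 0.6 from both wild types numbered 3: I: 938001 to 940000, I: 5558001 to 5560000, which lies next to the subtelomeric H2A.Z windows, and II: 2050001 to 2052000.

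The extract channel also showed strain marks. The unmatched mat probes had a median of -8.03 on Xap5 wild type 1, with 28 of 36 more than 3 below the array median, against 0.28 to 1.36 on the other arrays. At 1 probe beside mat1 (II: 2115500 to 2115559) the extract stood at -7.08 and -8.95 on the H2A.Z wild types, 0.75 on the array labelled xap5 deletion and -0.35 to 0.81 on the Xap5 arrays.

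In the authors' deposited table, the Xap5 column followed Xap5 wild type 1 (Pearson r = 0.987 across 40000 probes, against 0.459 with wild type 2), and the H2A.Z column followed H2A.Z wild type 1 (0.999, against 0.813 with wild type 2).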
